A study of Mus musculus with 47 samples.

How the data were processed

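Total RNA from the cells of 47 mouse T-cell lymphoblastic tumours was extracted with Trizol and turned into biotinylated cRNA by the standard Affymetrix protocol, per the labels' protocols. The authors deposited 1 linear MAS5 signal, a summary of hybridization intensities, per probe set and array, in arbitrary units, made with MAS5 per the submitters' processing notes. The version of MAS5, its scaling target and the build behind the probe sets are not given in the sources used here. As deposited, the signals of every array have the same trimmed mean with 2% of the values cut from each end (250.063 to 250.129), so the arrays had been scaled before deposit. The signals run from 0.0295601 to 22734.3, and the array medians from 49.6 to 106. A column of values holds 22690 probe sets, and no pair of arrays was identical.

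Probe sets for the Affymetrix controls (64) were kept apart and used only for 3'/5' signal ratios. Gene symbols were those of the platform table: 20380 probe sets carry 1 symbol, 691 carry several and 1555 carry none, and only the first kind was used. The gene table of assembly GRCm38.p6 holds the gene identifiers of 20351 of them and changed 0 symbols. A probe set was kept where its signal exceeded the array's median in at least 2 arrays. Of the probe sets kept, the one with the highest mean log2 value over all arrays stood for its gene, which left 8810 tested genes of 12393. Values were analysed as log2(signal + 15.9), where 15.9 is the 25th percentile of all deposited signals, with no further scaling between arrays. Genes with no probe set past this filter were not judged. The p53 gene is not analysed here.

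Tumours were grouped by the genetic background in the titles (14 backgrounds of 2 to 9 tumours) and by the TLX1 status in the labels (6 positive, 41 negative). The labels do not say that the tumours come from separate mice, so every p-value measures only the spread between samples. Fits used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, and "rose", "fell", "higher" and "lower" describe called genes. The first comparison set the mean of the 6 TLX1 positive tumours against the mean of the 41 negative ones. The second fitted 1 mean per background and set each against the unweighted mean of the other 13. From that fit came the 3 double against single comparisons, and 1 comparison of 6 backgrounds chosen for their link to E protein activity against the other 7 TLX1 negative backgrounds. All comparisons in that fit share 1 estimate of the spread, so a background of 2 tumours is assumed to vary like the rest. Values are log2 differences ± SE unless said otherwise, and where the dimmer group lies under the array medians their size depends on the pseudocount.

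Before the values were seen, 29 gene lists were fixed: spindle checkpoint and chromosome segregation, DNA damage checkpoint and repair, DNA replication, early thymic progenitor, double negative to beta selection, double positive, mature single positive, T cell receptor, T lineage regulators, Notch pathway, Wnt and beta-catenin targets, p53 targets, MYC targets, HOXA cluster and cofactors, leukaemia oncogenes, leukaemia tumour suppressors, ribosomal proteins, oxidative phosphorylation, glycolysis, interferon response, immediate early genes, apoptosis regulators, and markers of B cells, myeloid cells, erythroid cells, NK cells, thymic epithelium and stroma, endothelium and dendritic cells. Each held at least 5 tested genes and was tested with limma's camera with an estimated correlation between genes, with adjustment over the 29 lists. A count "over the list alone" repeats the adjustment within that list. Camera with a preset correlation of 0.01 and fry were alternatives. A separate list held the genes that the backgrounds target. The named genes followed a rule fixed in advance: the 12 largest called differences in each direction for TLX1, with 8 genes always named, the 2 largest in each direction per background, 3 for each double comparison, 5 for the E protein comparison, and up to 4 genes of lowest p per list. The 12 in each direction also had to exceed the mean array median in their higher group.

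Similarity was the Pearson correlation of gene-centred values. A one-sided permutation test with 100000 orders of the background labels counted tumours whose nearest neighbour shares their background. Control ratios were compared with a permutation test of 100000 orders. Chance groupings were examined with 100 splits that included the real one. Outlying samples were sought with Dixon's rule in groups of 6 and 9.

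Alternatives fixed in advance were a pseudocount of 1 or of 72.3 (the median), quantile normalization, no filter (12393 genes), a filter of 6 arrays (7912 genes), the probe set of largest interquartile range, eBayes without trend, the title number as a block, background as a random block, array weights, 14 background means, each sample or background left out, Spearman correlation and the 1000 most variable genes. Chosen after the data were seen were the 3'/5' ratio as a covariate, the removal of 3 TLX1 tumours with high ratios, of 3 tumours that stand apart from their background, and of the tumours whose *Lmo1* values go against their labels. The scripts were tested on simulated data with 100 genes changed by log2 1 and 100 by log2 2. The TLX1 comparison called 82% and 99% of them, Ikaros Plastic 67% and 86%, Pokemon 50% and 79%, and rag E2A against E2A knockout 32% and 63%. Apart from the changed genes, the backgrounds in these simulated data did not differ, and genes varied independently. The shares for TLX1 therefore do not measure what the real comparison can detect, where background differences enter the spread. In 10 simulations in which backgrounds differ and TLX1 has no effect of its own, the comparison of 6 with 41 tumours called 762 to 969 genes, and the fit with background as a random block called at most 1.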

Results

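Transcript levels were measured on Affymetrix arrays in 47 mouse T-cell lymphoblastic tumours from 14 lymphoma-prone genetic backgrounds. The groups are TLX1 transgenic (6 tumours), *Cdkn2a* knockout with retroviral insertional mutagenesis (9), p53 knockout, ThPOK transgenic, LMO1 transgenic, Tal1-LMO2 double transgenic, olig1-LMO1 double transgenic, Nup98HoxD13 transgenic, Ikaros Plastic and beta-catenin transgenic (3 each), and Tal1 transgenic, E2A knockout, rag E2A knockout and Pokemon transgenic (2 each). Only the TLX1 transgenic tumours carry the label TLX1 positive, so that label and that background cannot be told apart. Array medians ran from 49.6 to 106 signal units. Correlations of log2 values were 0.909 to 0.942 among TLX1 tumours, 0.889 to 0.983 among *Cdkn2a* knockout tumours and 0.810 to 0.933 among p53 knockout tumours.

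The 3'/5' signal ratio of control probe sets differed with TLX1 status. The *Gapdh* control probe sets gave a log2 3'/5' ratio of 1.36 ± 1.15 (mean ± SD, n = 6) in TLX1 positive tumours and −0.21 ± 0.25 (n = 41) in negative ones, a difference of 1.57 (permutation p = 1e-05, the smallest possible). *Actb* gave 1.66 ± 0.98 and 0.27 ± 0.25, a difference of 1.39 (permutation p = 1e-05). TLX1 tumours 2, 5 and 6 lie above every negative tumour for *Gapdh*, and tumours 2, 3, 5 and 6 do for *Actb*. A high ratio goes with degraded or incompletely copied RNA. The median signal did not differ (69.9 against 72.1, permutation p = 0.7).

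**Figure D1:**
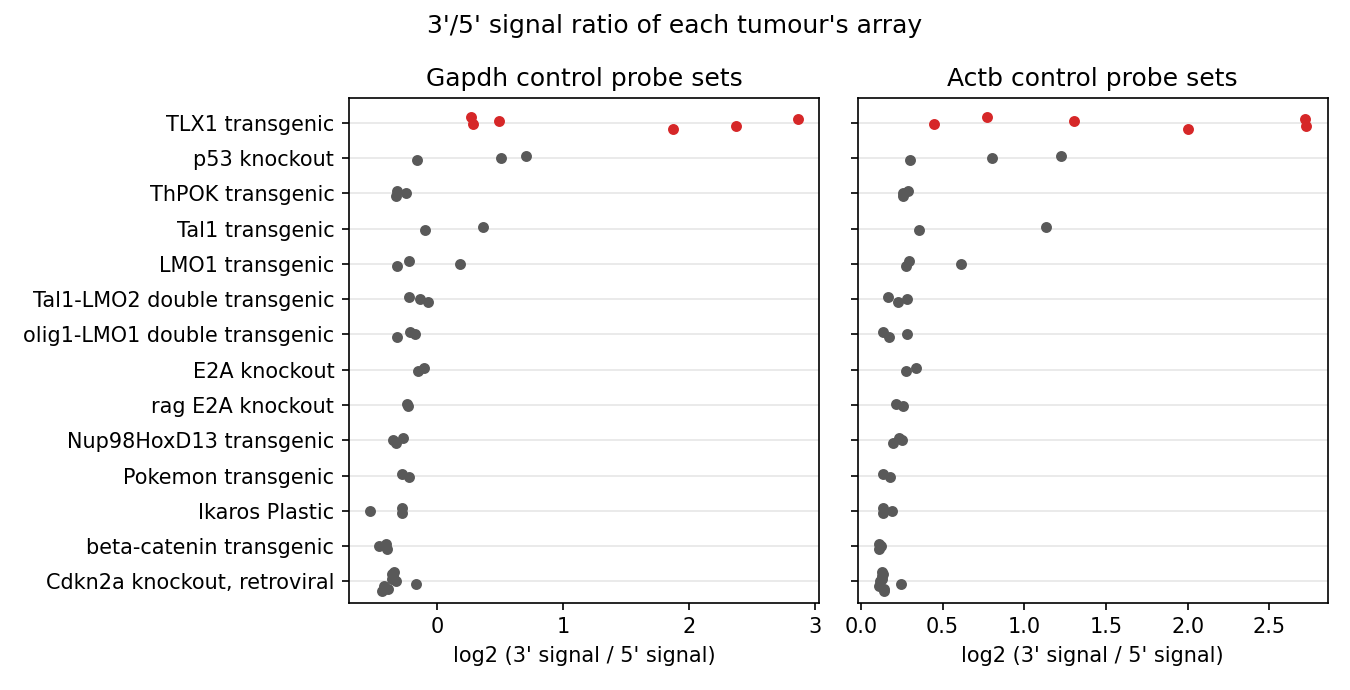
Log2 3'/5' signal ratio of the *Gapdh* and *Actb* control probe sets, 1 point per tumour, by labelled background (TLX1 transgenic in red). The 6 TLX1 transgenic tumours average 1.36 for *Gapdh*, against −0.21 in the 41 others.

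The genes that the backgrounds target were read first, because they check the labels. Of 13 tests of a targeted gene in its own background, 5 were called. *Lmo1* rose by 4.63 ± 0.51 in LMO1 transgenic tumours (n = 3, adjusted p = 2.5e-07) and *Zbtb7a*, which encodes Pokemon, by 4.10 ± 0.31 in Pokemon tumours (n = 2, adjusted p = 5.67e-12). *Tcf3*, which encodes E2A, fell by 1.28 ± 0.29 in E2A knockout tumours (n = 2, adjusted p = 0.00562). *Ikzf1*, which encodes Ikaros, rose by 1.25 ± 0.47 in Ikaros Plastic tumours (n = 3, adjusted p = 0.0471), and *Lmo2* fell by 1.62 ± 0.42 in Tal1-LMO2 tumours (n = 3, adjusted p = 0.0136; signals 13.6 to 19.8). After quantile normalization neither of these last calls holds (*Ikzf1* 1.23, *Lmo2* −1.32), nor does *Ikzf1* with a pseudocount of 1 (1.38) or *Lmo2* with one at the median (−0.88). *Tcf3* was −0.97 ± 0.29 in rag E2A knockout tumours (n = 2, adjusted p = 0.0752, or 0.00473 over the list alone), the only call gained when the adjustment covered the list alone. Not called were *Zbtb7b*, which encodes ThPOK (−0.02 ± 0.53, adjusted p = 0.987, and 0.20 with a pseudocount of 1), *Nup98* (0.41 ± 0.18), *Ctnnb1* (0.22 ± 0.13), *Cdkn2a* (−0.30 ± 0.23), *Rag1* (0.57 ± 1.10) and *Rag2* (1.00 ± 0.80). A second *Zbtb7b* probe set, which the fit did not use, exceeds the array median in 9 arrays, among them all 3 ThPOK tumours (97.4 to 124, against 2.83 to 187 elsewhere). *Rag1* read 1609 to 2067 and *Rag2* 131 to 148 in tumours labelled rag E2A knockout, so neither probe set shows a loss. *Tal1*, *Olig1*, *Hoxd13* and *Tlx1* were below the filter, and the *Tlx1* probe set read 7.14 to 41.5 in TLX1 tumours against 1.53 to 160 elsewhere. A probe set outside a deleted part, or against a mouse sequence where the transgene is of another species, checks nothing.

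*Lmo1* goes against 2 labels, and *Lmo2* does not support the label Tal1-LMO2. The *Lmo1* signal was 522 to 2344 in LMO1 transgenic tumours and 586 to 2526 in the 3 tumours labelled Nup98HoxD13. In the 3 tumours labelled olig1-LMO1 it was 11.1 to 34.3 (log2 difference −0.97 ± 0.51, adjusted p = 0.452), and the other 38 tumours stay at or below 249. *Hoxc4*, a homeobox gene, read 315 and 710 in tumours 2 and 3 labelled olig1-LMO1 and 1.95 in tumour 1. Both groups are therefore called by their label below, and directions drawn from them depend on labels that *Lmo1* goes against.

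**Figure D2:**
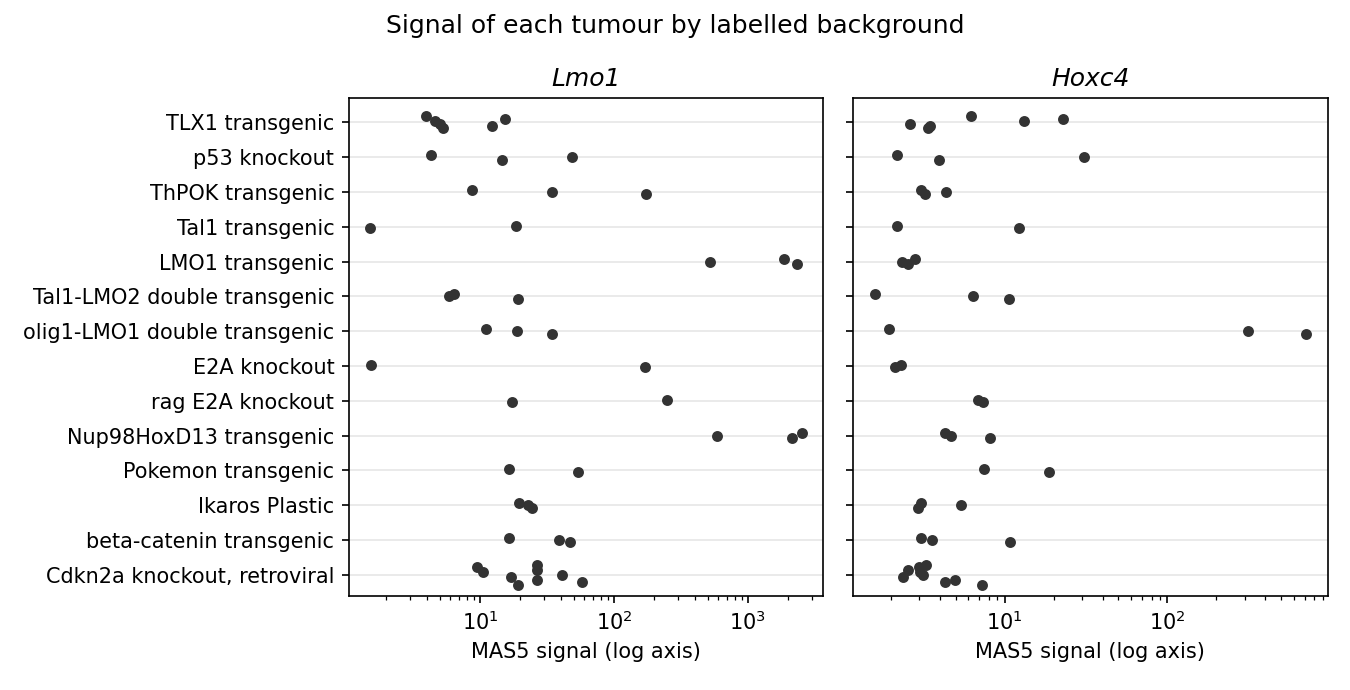
MAS5 signal (log axis) of *Lmo1* and *Hoxc4* in each of 47 tumours by labelled background, 1 point per tumour. *Lmo1* is 586 to 2526 in tumours labelled Nup98HoxD13 and 11.1 to 34.3 in tumours labelled olig1-LMO1.

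TLX1 is a homeobox transcription factor that drives T-cell leukaemia, and the labels ask what sets the 6 TLX1 positive tumours apart from 41 TLX1 negative ones. *Adarb1*, an RNA-editing deaminase, rose by 2.95 ± 0.30 (adjusted p = 1.71e-09). *Dlx1*, a homeobox gene, rose by 3.32 ± 0.53 (adjusted p = 3.04e-05). *Gsdme*, which encodes a pore-forming gasdermin, fell by 2.83 ± 0.37 (adjusted p = 1.83e-06). *Bcl11b*, a T lineage transcription factor and tumour suppressor, was higher by 1.42 ± 0.44 (adjusted p = 0.0167), above 12 of the 13 negative background means. *Myc* fell by 1.54 ± 0.31 (adjusted p = 4.2e-04).

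Among the largest rises were *Igha*, an immunoglobulin constant region (3.82 ± 0.81), *Plagl1* (3.13 ± 0.89), *Myl10* (3.00 ± 0.55), *Bex1* (2.93 ± 1.00), the T cell receptor segment *Trgv4* (2.88 ± 0.80), *Dppa2* (2.73 ± 0.40), *Smim3* (2.69 ± 0.40), the actin-severing *Gsn* (2.65 ± 0.55) and the macrophage genes *Retnla* (2.85 ± 0.64) and *Chil3* (2.63 ± 0.64). Among the largest falls were *Ptp4a2* (−3.21 ± 0.47), *AI506816* (−2.75 ± 0.99), the major histocompatibility genes *H2-T3* (−2.95 ± 0.80) and *H2-Q2* (−2.77 ± 0.80), *Zfp207* (−2.63 ± 0.44), *Igf2bp3* (−2.35 ± 0.70) and *Ctse* (−2.14 ± 0.61). The T-cell genes *Cd8b1* (−2.10 ± 0.58), *Lef1* (−2.08 ± 0.53) and *Ikzf1* (−2.07 ± 0.49) and the transcription factor *Sp3* (−2.07 ± 0.37) also fell. The labels give no mouse strain, H2 genes differ between strains, and *AI506816* is equally low in 6 negative backgrounds. The *Bex1* call was lost in 10 of 35 alternatives, that of *AI506816* in 16 and that of *Bcl11b* in 6. Other probe sets disagree in sign for *Ptp4a2* (2 of 3) and *Zfp207* (1 of 3). A second *Adarb1* probe set, below the filter but brighter on average, gives 0.34 and is not called when no filter is applied, and the *Ctse* probe set of largest interquartile range gives −0.42, not called. *Chek1* (−0.25 ± 0.21, adjusted p = 0.426), *Cdkn2a* (0.34 ± 0.39, adjusted p = 0.562) and *Notch1* (0.25 ± 0.86, adjusted p = 0.864, its other probe set opposite in sign) were not called.

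In total 1889 of 8810 genes were called, 1108 higher and 781 lower (440 by at least 2-fold, 293 up and 147 down). The count depends on how the background is treated. With background as a random block 2 genes remain, *Adarb1* (2.99 ± 0.44, adjusted p = 0.000145) and *Gsdme* (−2.84 ± 0.57, adjusted p = 0.0328), with 997 at an unadjusted p under 0.05. Simulated backgrounds with no TLX1 effect gave 762 to 969 calls in the same comparison, so a called gene cannot be assigned to TLX1 rather than to its background. The count also depends on the tumours of high 3'/5' ratio, in alternatives chosen after the data were seen: 132 genes are called without TLX1 tumours 2, 5 and 6, and 1388 without tumours 1, 3 and 4. Leaving out TLX1 tumour 2 alone gives 1224. With the ratio as a covariate 6 genes are called (*Adarb1*, *Kmt2c*, *Rnase2a*, *Sart3*, *Smim3* and *Usp20*, all higher). The ratio goes with TLX1 status, so the covariate can also take up a TLX1 difference, and it widens the median SE of the higher genes from 0.20 to 0.30. Under the covariate the 1108 higher genes went from a median of 0.74 to 0.44 and the 781 lower genes from −0.68 to −0.20. *Dlx1* held its size (3.39 ± 0.84, adjusted p = 0.15), *Adarb1* stood at 2.10 ± 0.44, and *Myc* (−0.03 ± 0.40), *Myl10* (0.56 ± 0.73), *Lef1* (−0.06 ± 0.76), *Ptp4a2* (−0.84 ± 0.60), *Sp3* (−0.40 ± 0.49) and *Cd8b1* (−0.53 ± 0.87) lost most of theirs. *Ikzf1* turned to 0.38 ± 0.62 and *Ctse* to 0.31 ± 0.85. Of the 12 largest rises 2 stay called with the covariate, and of the 12 largest falls 0. Some uncalled rises kept their size with a wider SE: *Plagl1* 3.50 ± 1.41, *Bex1* 3.34 ± 1.58, *Trgv4* 3.82 ± 1.25, *Retnla* 3.83 ± 0.99 and *Bcl11b* 1.39 ± 0.70. Other genes shrank, such as *Dppa2* (1.29 ± 0.57) and *Zfp207* (−0.69 ± 0.59). Without tumours 2, 5 and 6 all 12 rises and all 12 falls keep their direction, though tumours 1, 3 and 4 helped choose them.

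**Figure D3:**
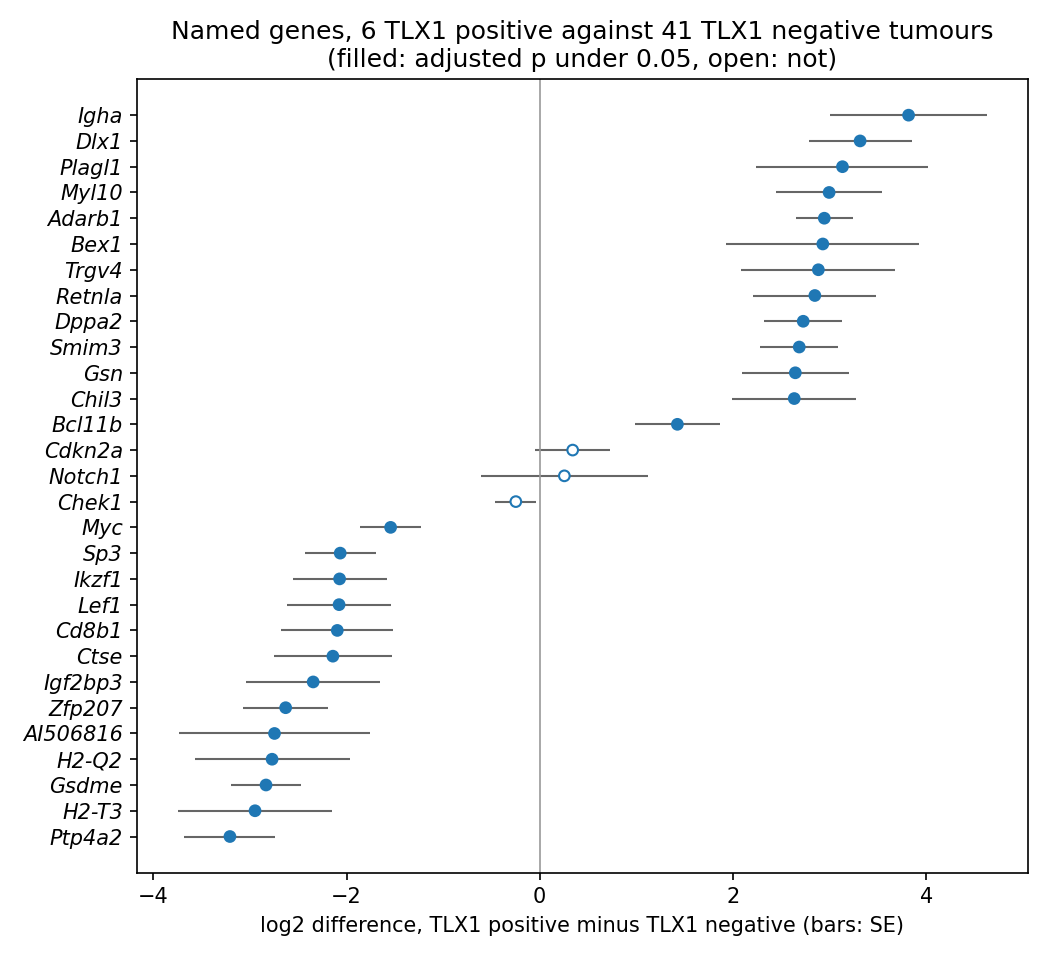
Log2 difference (± SE) of the named genes between 6 TLX1 positive and 41 TLX1 negative tumours, with filled points for an adjusted p under 0.05. *Igha* leads at 3.82 and *Ptp4a2* is lowest at −3.21.

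None of the 29 gene lists was called for TLX1 with an estimated correlation (0 of 29, lowest adjusted p = 0.92, 0 at an unadjusted p under 0.05), against 5 with the preset correlation and 2 with fry. Of 23 MYC targets, a list of mixed function, 9 fell and 0 rose (9 over the list alone), among them *Nme1* (−1.71 ± 0.29) and *Eif4a1* (−1.40 ± 0.25). The list's adjusted p was 2.28e-05 with the preset correlation and 0.0359 with fry. With the covariate *Nme1* is −0.93 ± 0.43 and *Eif4a1* −0.19 ± 0.32, neither called. Of 17 apoptosis regulators 8 rose and 0 fell (*Fas* 1.01 ± 0.35, *Birc3* 0.91 ± 0.26, *Casp9* 0.77 ± 0.23; adjusted p = 0.00234 with fry). Adjustment over a list alone left the counts as they were in 23 of 29 lists. The high 3'/5' ratios belong to TLX1 tumours 2, 5 and 6, and the list means follow them only in part. MYC targets average −0.81 and −0.57 in tumours 2 and 5, but −0.22 in tumour 6 and −0.77 in tumour 4. Apoptosis regulators average 0.48 and 0.46 in tumours 3 and 4, and 0.19 in tumour 6. With the covariate *Fas* is 1.29 ± 0.55, *Birc3* 0.98 ± 0.40 and *Casp9* 0.38 ± 0.36, none called.

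Few cell division and repair genes were called. Of 45 spindle checkpoint and chromosome segregation genes 5 fell and 1 rose (4 and 1 over the list alone). Among them were *Stag1* (−1.05 ± 0.21), *Plk1* (−0.71), *Mad2l1* (−0.66) and *Kif23* (0.69). Camera with the preset correlation called this list and the DNA replication list lower (adjusted p = 0.0491 each). It did not call the DNA damage list (adjusted p = 0.0583). Of 27 DNA damage genes 4 fell and 1 rose (*Tlk2* −0.96 ± 0.20, *Hus1* −0.56), and of 30 DNA replication genes 3 fell and 1 rose (3 and 0; *Orc1* −0.72). Of 21 p53 targets 2 rose (0 over the list alone; *Fas*, *Apaf1* 0.46), with a median of 0.03 against a test pointing down.

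T-cell stage genes gave a mixed picture. Of 17 T lineage regulators 3 rose (*Bcl11b*, *Gata3* 1.24 ± 0.35, *Zbtb17* 0.56) and 5 fell (6 over the list alone; *Lef1*, *Ikzf1*, *Tox* −1.34, *Runx1* −1.19). The early thymic progenitor list had 1 rise in 15 (*Lyl1* 1.95 ± 0.34), the double negative list 1 in 14 (0 over the list alone; *Il7r* 1.54 ± 0.55) and the mature single positive list 4 in 19 (*Il7r*, *Stat4* 1.44, *Ifngr1* 1.18). The double positive list had 1 fall in 16 (*Cd8b1*), with a median of 0.15 but a mean of −0.24. In the T cell receptor list 0 of 20 were called. Notch pathway genes had 1 rise (*Hey1* 0.92) and 2 falls (*Trib2* −1.83, *Myc*) in 16, but the TLX1 tumours were divided. The Notch list mean was −0.82, −0.99 and −1.28 in tumours 1, 2 and 6, and 0.56, 1.04 and 0.46 in tumours 3, 4 and 5. The double negative list, which shares *Notch1* and other genes with it, divided the same tumours (−0.66, −0.51 and −1.24, against 0.63, 0.70 and 0.68). Wnt and beta-catenin targets had 2 falls in 13 (*Lef1*, *Myc*). The HOXA list had 0 called of 5, the oncogenes 1 rise and 1 fall in 10, and the tumour suppressors 3 and 3 in 18, with a median of 0.15 and a mean of −0.03.

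Ribosomal protein genes (0 of 20 called), oxidative phosphorylation (2 rises and 1 fall in 29, median 0.06, test pointing down), glycolysis (1 and 1 in 14, median −0.01, mean 0.05) and immediate early genes (1 and 1 in 19) hardly moved. Interferon response genes had 3 rises (*Mx1* 1.45, *Bst2* 1.32, *Tap1* 1.06) and 1 fall (*Stat2* −0.69) in 18. Some markers of other cells rose, though no such list was called with an estimated correlation and most members were not called. Camera with the preset correlation called the thymic epithelium and stroma list higher (adjusted p = 0.0491). Myeloid markers had 7 rises in 23 (*Camp* 2.58 ± 0.59, *S100a9* 2.34, *Ctsg* 2.09), thymic epithelium and stroma 2 in 18 (*Krt18* 1.87, *Ccl25* 1.14), endothelium 2 in 12 (*Tie1* 1.47, *Vwf* 1.26), and B cells 2 in 11 (0 over the list alone; *Jchain* 2.26, *Ighm* 1.94). NK cells had 1 in 9 (*Tbx21* 1.79), dendritic cells 1 in 9 (*Bst2*) and erythroid cells 0 in 8. Without TLX1 tumours 2, 5 and 6 the granule genes shrink, with *Camp* at 0.55 ± 0.55 and *Ctsg* at 0.40. The mean of the myeloid list is 3.10 in tumour 2 and 1.29 in tumour 5. It is −0.38 in tumour 6 and −0.05, 0.19 and 0.09 in tumours 1, 3 and 4, so tumour 2 carries most of the rise.

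The second comparison asks what sets each background apart from the mean of the other 13. A gene named for 1 background can be as high or as low in another. The number of called genes ran from 58 to 2777, and the largest groups had the highest counts. TLX1 tumours (n = 6) had 2777, 1672 higher and 1105 lower, again with *Igha* (3.85 ± 0.46), *Bex1* (3.21), *Ptp4a2* (−3.27) and *H2-T3* (−3.20) at the extremes. With the 3'/5' ratio as a covariate, chosen after the data were seen, 309 genes are called. No list was called with an estimated correlation (lowest adjusted p = 0.694).

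**Figure D4:**
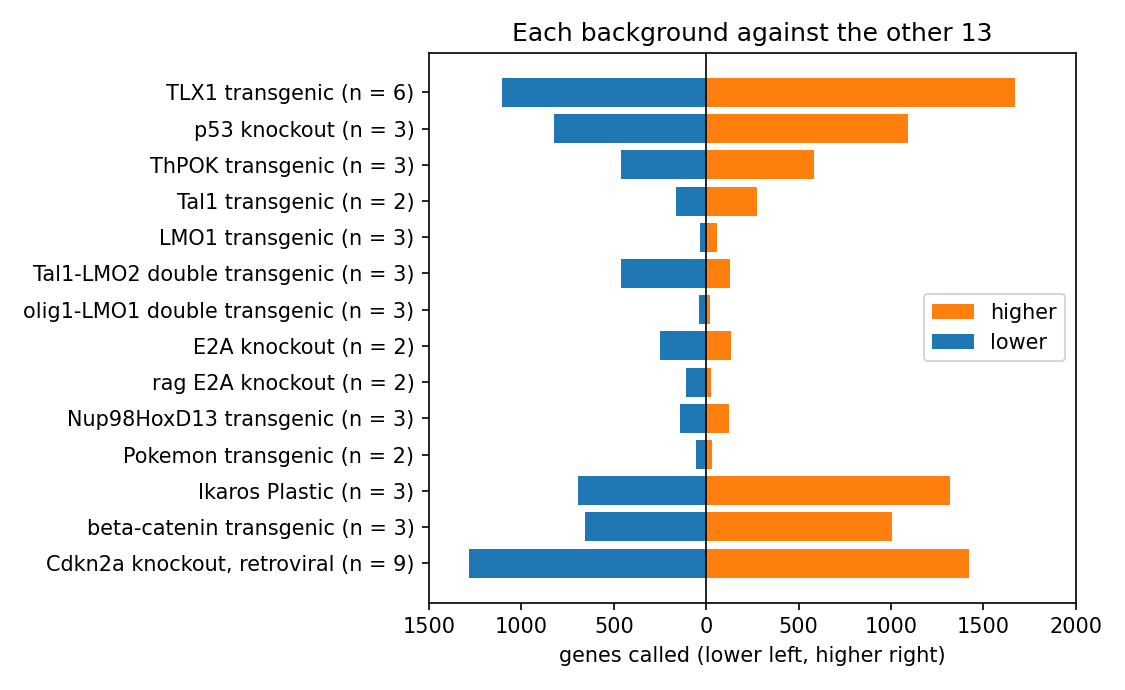
Genes called in each background against the other 13 (bars right of 0: higher, left: lower), with the number of tumours. Counts run from 58 in tumours labelled olig1-LMO1 to 2777 in TLX1 transgenic tumours.

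p53 knockout tumours (n = 3) were divided, and tumour 2 carries much of what follows. *Tie1* (2.68 ± 0.40) and *Cldn5* (2.38 ± 0.54) were among 11 of 12 endothelial markers that rose (12 over the list alone; adjusted p = 0.478 with an estimated correlation), and 7 of 18 stroma markers rose as well (7 over the list alone; *Sparc* 2.47 ± 0.56, *Col6a1* 2.18 ± 0.40; adjusted p = 0.501). *Cacng4* (3.17 ± 0.51) and the interferon-induced *Rsad2* (2.94 ± 0.44) rose most, and *Cap1* (−3.40 ± 0.38) and *Erdr1* (−3.12 ± 0.51) fell most. T cell receptor genes were lower in 7 of 20 (10 over the list alone; *Cd3g* −1.94 ± 0.46, *Zap70* −1.59; adjusted p = 0.478), and DNA replication genes in 14 of 30 (16 over the list alone; adjusted p = 0.501). Of 21 p53 targets, 2 rose and 3 fell (2 and 7 over the list alone), among them *Plk2* (1.62 ± 0.43), *Trp53inp1* (−1.18 ± 0.33) and *Ccng1* (−0.84 ± 0.26). Ribosomal protein genes were lower in 16 of 20, and in 3 of 20 after quantile normalization. In all 1915 genes were called (1092 higher, 823 lower). Without tumour 2 the count is 580, with 1 of 12 endothelial markers higher (*Tie1* 1.33 ± 0.27), 0 of 18 stroma markers higher, and 0 of 20 T cell receptor and 0 of 30 DNA replication genes lower. Of 21 p53 targets 0 are then higher and 2 lower. *Cldn5* (0.43 ± 0.32), *Sparc* (1.51 ± 0.62), *Col6a1* (0.98 ± 0.34), *Cd3g* (−0.29 ± 0.27), *Zap70* (−0.09 ± 0.26), *Plk2* (0.14 ± 0.29), *Trp53inp1* (−0.16 ± 0.27) and *Ccng1* (−0.53 ± 0.31) are then not called. *Cacng4* (3.22 ± 0.62), *Rsad2* (2.03 ± 0.46), *Cap1* (−3.41 ± 0.47) and *Erdr1* (−3.65 ± 0.60) still are.

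ThPOK directs thymocytes to the CD4 lineage and represses *Cd8a*. *Cd8a* fell in ThPOK transgenic tumours (n = 3) to signals of 23.1 to 47.5, under the array medians, so its log2 difference (−4.61 ± 0.81, adjusted p = 0.000289) depends on the pseudocount. *Erdr1* fell by 4.64 ± 0.51, while *Stc1* (2.90 ± 0.51) and *Bves* (2.87 ± 0.52) rose most. *Runx3*, the CD8 lineage factor, was higher (0.81 ± 0.25), *Id2* was higher (1.44 ± 0.48) and *Ets1* lower (−1.27 ± 0.18). Of 23 myeloid markers 8 rose (10 over the list alone; *C1qc* 1.79 ± 0.34, *Cd68* 1.23 ± 0.26; adjusted p = 0.98 with an estimated correlation). The total was 1041 genes (582 higher, 459 lower), and 475, 367 and 274 without tumours 1, 2 and 3.

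In Tal1 transgenic tumours (n = 2) *Ifi204* (2.95 ± 0.72) and *H2-T18* (2.91 ± 0.89) rose most, and *Cytip* (−3.76 ± 0.65) and *Mndal* (−3.52 ± 0.82) fell most. *Hes1*, a Notch target, fell by 1.79 ± 0.53. Ribosomal protein genes were higher in 16 of 20 (17 over the list alone; *Rps3* 1.18 ± 0.14; adjusted p = 0.0621 with an estimated correlation) and oxidative phosphorylation genes in 12 of 29 (18 over the list alone; *Cox7a2* 1.20 ± 0.16; adjusted p = 0.0981). Quantile normalization left 0 of either list higher and took the median of the ribosomal list from 0.87 to 0.01 and that of the other from 0.53 to 0.13, so the size of these gains depends on the scaling. The total was 437 genes (273 higher, 164 lower), 127 and 277 without tumours 1 and 2, and 101 after quantile normalization.

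LMO1 transgenic tumours (n = 3) were marked by *Lmo1* itself (4.63 ± 0.51). *Glycam1* rose by 3.83 ± 1.01 (adjusted p = 0.0498), and *AI506816* (−3.02 ± 0.22) and *H2-D1* (−2.24 ± 0.51) fell. B cell markers were higher in 2 of 11 (8 over the list alone; *Jchain* 3.30 ± 0.69, *Cd79a* 1.96 ± 0.51; adjusted p = 0.214 with an estimated correlation), with a list mean of 0.06 in tumour 1 against 2.39 and 1.31 in tumours 2 and 3. The class II gene *H2-Eb1* (2.12 ± 0.54) and the stress gene *Zfp36* (1.27 ± 0.33) were also higher. There were 91 called genes (59 higher, 32 lower), 42, 17 and 13 without tumours 1, 2 and 3, and 153 without the tumours labelled Nup98HoxD13 and olig1-LMO1, an alternative chosen after the data were seen.

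Tal1-LMO2 double transgenic tumours (n = 3) had lower thymic epithelium and stroma markers. *Sparc* (−3.71 ± 0.56) and *Col3a1* (−3.57 ± 0.51) were among 10 of 18 that fell (11 over the list alone), a list called with an estimated correlation (adjusted p = 0.0305). Myeloid markers fell in 12 of 23 (13 over the list alone; *C1qc* −2.45 ± 0.34; adjusted p = 0.116). *H2-T3* (3.11 ± 0.66) and *Cd7* (2.96 ± 0.69) rose most, and *Ccl8* (−3.84 ± 0.64) and *Fabp4* (−3.79 ± 0.50) fell most. The total was 588 genes (127 higher, 461 lower), 325, 261 and 150 without tumours 1, 2 and 3, and 265 after quantile normalization.

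Against Tal1 single transgenic tumours (3 against 2), which the label sets apart by LMO2 although mouse *Lmo2* is low in the double transgenic tumours, *Sparc* (−5.13 ± 0.85), *Fabp4* (−4.01 ± 0.77) and *Mgp* (−3.74 ± 0.83) fell most. The glucose transporter gene *Slc2a3* (4.18 ± 0.71), *Agfg1* (2.82 ± 0.65) and *Myo1g* (1.52 ± 0.35) rose. The stroma list was called lower (adjusted p = 0.0484), with 3 of 18 genes down and 8 over the list alone. In all 41 genes were called, 4 higher and 37 lower (9.76% higher), and 5 after quantile normalization (20.0% higher). Without Tal1-LMO2 tumours 1, 2 and 3 the count is 13, 19 and 4, and without Tal1 tumour 1 it is 3.

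As a group mean, the 3 tumours labelled olig1-LMO1 had higher HOXA cluster genes and cofactors: *Hoxa7* (2.25 ± 0.41), *Pbx3* (2.17 ± 0.41) and *Hoxa5* (1.72 ± 0.40) made 3 of 5 (4 over the list alone), and the list was called (adjusted p = 0.0160). The rise comes from tumours 2 and 3 (*Hoxa5* 185 and 208, *Pbx3* 600 and 909). Tumour 1 lies within the range of the other backgrounds (*Hoxa5* 1.70, *Hoxa7* 4.67, *Pbx3* 115). *AI506816* (2.96 ± 0.22) and *Hoxc4* (2.91 ± 0.45) rose most. *Mndal* (−3.30 ± 0.68) fell, as did the class II antigen genes *H2-Eb1* (−3.14 ± 0.54), *H2-Aa* (−2.57 ± 0.48) and *Cd74* (−2.54 ± 0.54). The total was 58 genes (18 higher, 40 lower), 29, 16 and 22 without tumours 1, 2 and 3, and 38 after quantile normalization. These directions depend on labels that *Lmo1* goes against.

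Against LMO1 transgenic tumours (3 against 3), the tumours labelled olig1-LMO1 had more *AI506816* (5.55 ± 0.29), *Gdpd3* (4.31 ± 0.85) and *Dlx1* (3.38 ± 0.51). *Mndal* (−6.56 ± 0.93), *Igkv8-30* (−5.66 ± 0.86) and *Jchain* (−5.41 ± 0.93) fell most. The HOXA list was called higher (3 of 5 genes, 4 over the list alone; adjusted p = 0.0126), again through tumours 2 and 3. Of 85 called genes 27 were higher and 58 lower. Leaving out tumour 3 labelled olig1-LMO1 gives 46, LMO1 tumour 2 gives 37, LMO1 tumour 3 gives 47, and tumours 1 and 2 labelled olig1-LMO1 give 52 and 51.

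E2A knockout tumours (n = 2) lack an E protein that restrains thymocyte growth. Beside *Tcf3*, *Igkv8-30* (−3.89 ± 0.76) and *Gpx3* (−3.74 ± 0.58) fell, and *H2-T3* (3.25 ± 0.80) and *H2-T18* (3.14 ± 0.89) rose. Myeloid markers fell in 9 of 23 (10 over the list alone; *C1qc* −3.13 ± 0.41, *Lyz1* −2.36 ± 0.29; adjusted p = 0.108 with an estimated correlation) and stroma markers in 9 of 18 (9 over the list alone; *Sparc* −3.70 ± 0.68; adjusted p = 0.0619). Ribosomal protein genes were higher in 15 of 20 (adjusted p = 0.108) and in 0 of 20 after quantile normalization, which moved the median of all genes from −0.07 to 0.04. The total was 382 genes, 34.8% of them higher, against 153 and 21.6% after quantile normalization. Without tumour 1 the count is 23, and without tumour 2 it is 233.

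In tumours labelled rag E2A knockout (n = 2) *H2-T18* (3.81 ± 0.89) and *H2-T3* (3.45 ± 0.80) rose most, and *Mndal* (−3.91 ± 0.82) and *Igkv8-30* (−3.85 ± 0.76) fell most. *Id3*, an inhibitor of E proteins, fell by 2.92 ± 0.70 and *Nr4a1*, a gene induced by T cell receptor signals, by 2.38 ± 0.60. Stroma markers fell in 3 of 18 (9 over the list alone; *Cxcl12* −2.25 ± 0.51, *Dcn* −2.07 ± 0.50; adjusted p = 0.396 with an estimated correlation). The total was 137 genes, 26 higher and 111 lower (19.0% higher), against 49 and 40.8% after quantile normalization, and 11 and 40 without tumours 1 and 2. Against E2A knockout tumours (2 against 2), which asks what the added rag label brings although *Rag1* and *Rag2* transcripts are present, 4 genes were called: the histone genes *H3c4* (2.59 ± 0.36) and *H3c7* (1.87 ± 0.35) and *Selenop* (2.25 ± 0.44) rose and *Zfp982* (−2.85 ± 0.52) fell. That count is 7 without rag E2A tumour 2 and 16 without E2A tumour 2.

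The 3 tumours labelled Nup98HoxD13 were marked by *Lmo1* (4.81 ± 0.51, adjusted p = 9.56e-08) and *Gfra1* (3.11 ± 0.55), while *Erdr1* (−3.14 ± 0.51) and *Tmem87a* (−3.02 ± 0.49) fell. The Nup98HoxD13 fusion is known to raise HOXA genes, yet 0 of 5 HOXA genes were called (adjusted p = 0.952). Ribosomal protein genes were lower in 17 of 20 (19 over the list alone; *Rps3* −0.73 ± 0.12; adjusted p = 0.131 with an estimated correlation) and in 0 of 20 after quantile normalization. The total was 265 genes (121 higher, 144 lower), 140, 142 and 67 without tumours 1, 2 and 3, and 101 after quantile normalization. These directions too depend on labels that *Lmo1* goes against.

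Pokemon transgenic tumours (n = 2) were marked by *Zbtb7a* (4.10 ± 0.31) and *Gm6958* (4.03 ± 0.70). *Erdr1* (−4.39 ± 0.62) and *AI506816* (−3.09 ± 0.26) fell most. The tumour suppressors *Cnot3* (−1.02 ± 0.24) and *Nf1* (−0.86 ± 0.21) and the glycolysis gene *Aldoa* (−1.03 ± 0.24) were lower, and 0 of 17 T lineage regulators were called. The total was 84 genes (31 higher, 53 lower), and 12 and 6 without tumours 1 and 2.

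In Ikaros Plastic tumours (n = 3) *Fos* rose by 4.36 ± 0.41 and *Jun* by 2.29 ± 0.33, among 14 of 19 immediate early genes (15 over the list alone; adjusted p = 0.174 with an estimated correlation). Stroma and epithelium markers rose in 12 of 18 (14 over the list alone; *Krt18* 3.03 ± 0.68, *Pdgfrb* 2.75 ± 0.52; adjusted p = 0.174). Their list mean is highest in tumour 2 (1.88, against 0.62 and 1.06 in tumours 1 and 3). The gland genes *Mucl2* (6.80 ± 0.92) and *Scgb2b27* (5.66 ± 0.90) rose most, highest in tumour 2 (*Scgb2b27* 8768, against 937 and 165), and *Ly6d* (−3.33 ± 1.11) and *Ddc* (−2.62 ± 0.93) fell most. The Notch genes *Igf1r* (1.77 ± 0.38) and *Hes1* (1.64 ± 0.44) were higher and *Gfi1* (−1.40 ± 0.48) lower. Ribosomal protein genes were lower in 19 of 20, and in 2 of 20 after quantile normalization. Of 2013 called genes 65.6% were higher, against 41.3% of 1616 after quantile normalization, which moved the median of all genes from 0.09 to −0.08. Without tumour 2 the count is 526.

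In beta-catenin transgenic tumours (n = 3) *Apcdd1* (4.74 ± 0.83), *Sp5* (3.67 ± 0.54), *Prox1* (3.03 ± 0.41) and *Notum* (2.72 ± 0.34) were among 8 of 13 Wnt and beta-catenin targets that rose (11 over the list alone; adjusted p = 0.0877 with an estimated correlation). The muscle gene *Tnni1* (5.67 ± 0.35) and the Wnt inhibitor *Wif1* (5.44 ± 0.71) rose most. *Notch1* (−4.09 ± 0.65, adjusted p = 2.34e-05) and *Hdgfl3* (−4.08 ± 0.82) fell most. Notch pathway genes were lower in 6 and higher in 2 of 16 (8 and 3 over the list alone; *Ptcra* −3.67 ± 0.95, *Hes1* −1.93 ± 0.44; adjusted p = 0.339). Dendritic cell markers rose in 8 of 9 (8 over the list alone; *Ccl22* 3.47 ± 0.30; adjusted p = 0.261) and B cell markers in 7 of 11 (9 over the list alone; *Ms4a1* 2.53 ± 0.52; adjusted p = 0.32). Of 1657 called genes 60.5% were higher, against 45.1% of 1588 after quantile normalization. Without tumours 1, 2 and 3 the count is 921, 944 and 718.

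*Cdkn2a* knockout tumours with retroviral insertions (n = 9) had low *Notch3*, and 8 of 9 had low *Notch1* and *Dtx1* (tumour 7: 1537 and 2175). *Notch1* fell by 3.44 ± 0.40 (adjusted p = 7.31e-08), *Dtx1* by 3.14 ± 0.58 and *Notch3* by 2.46 ± 0.34, and 10 of 16 Notch pathway genes were lower and 2 higher (10 and 2 over the list alone; adjusted p = 0.786 with an estimated correlation). Double negative stage genes were lower in 7 of 14 (7 over the list alone; adjusted p = 0.319). *Myc* rose by 1.24 ± 0.19, with 7 of 23 MYC targets higher (*Polr1b* 0.75 ± 0.17, *Ddx21* 0.65 ± 0.09; adjusted p = 0.786). Of 21 p53 targets 6 rose and 2 fell (6 and 3 over the list alone; *Bbc3* 1.07 ± 0.22, *Fas* 0.76 ± 0.22). *AI506816* (2.93 ± 0.13) and *Wwc1* (2.88 ± 0.40) rose most, and *Mndal* (−3.47 ± 0.42) fell most. The highest *Wwc1* mean of another background was log2 10.9, above the 8.71 of *Cdkn2a* knockout tumours. The total was 2704 genes (1420 higher, 1284 lower).

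**Figure D5:**
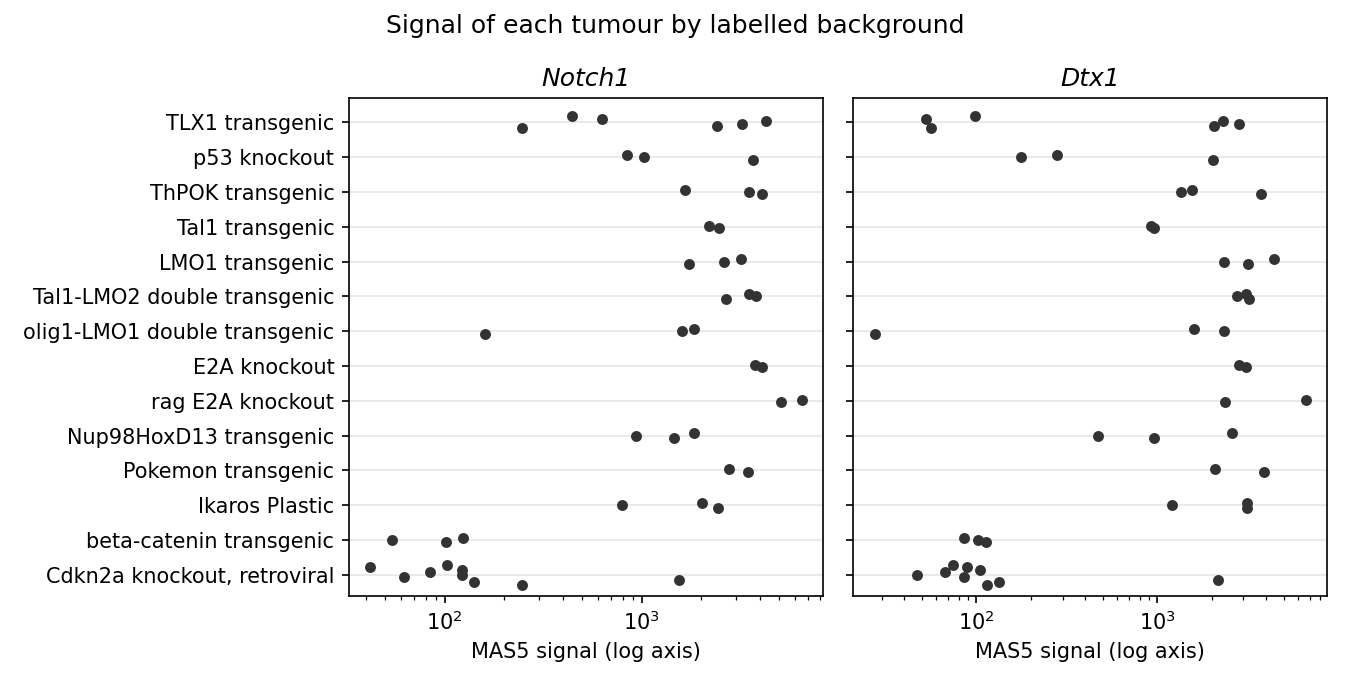
MAS5 signal (log axis) of *Notch1* and *Dtx1* in each of 47 tumours by labelled background, 1 point per tumour. *Notch1* is 54.3 to 124 in beta-catenin tumours and at most 246 in 8 of 9 *Cdkn2a* knockout tumours, against a median of 2426 (lowest 160) in the 35 tumours of other backgrounds.

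Across all backgrounds 2 list tests were called, the stroma list in Tal1-LMO2 tumours and the HOXA list in tumours labelled olig1-LMO1, where 2 of 3 tumours carry it. Whole profiles followed background. In 30 of 47 tumours the most correlated other tumour had the same background, against 3.44 by chance (one-sided permutation p = 1e-05, the smallest possible). All tumours of ThPOK, LMO1 and beta-catenin transgenic mice (3 of 3 each) and of Pokemon transgenic mice (2 of 2) were nearest to their own kind, as were 8 of 9 *Cdkn2a* knockout and 4 of 6 TLX1 tumours. None of the p53 knockout, Tal1, Tal1-LMO2 or E2A knockout tumours was. The closest pairs of backgrounds were Tal1-LMO2 with E2A knockout (mean r = 0.484), E2A with rag E2A knockout (0.459) and Tal1-LMO2 with rag E2A knockout (0.420).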

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

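Values below were singled out because 1 tumour lies far from the rest of its group, or because control probe sets that no comparison uses read above every TLX1 negative tumour. Of 92 groups of values examined for a far tumour, 17 had one, where chance gives about 1 in 20 (4.6). Among TLX1 tumours, *Bex1* was low in tumour 3 (log2 6.61), *Trgv4* in tumour 6 (5.77) and *Cd8b1* in tumour 2 (5.08), and *Cdkn2a* was high in tumour 1 (7.46). The mean of the T cell receptor list was low in TLX1 tumour 2 (−0.86) and that of the dendritic cell list high in tumour 5 (1.98).

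*Cdkn2a* knockout tumour 7 stood apart from the other 8 for *Notch1* (log2 10.6), for the Notch pathway list (mean 0.0313) and for the double negative list (−0.0149). Tumour 8 stood apart for 6 lists: spindle checkpoint (−0.55), DNA damage (−0.32), DNA replication (−0.52), early thymic progenitor (0.82), HOXA (0.53) and endothelial markers (0.64). Tumour 9 was high for T lineage regulators (0.49) and tumour 2 low for apoptosis regulators (−0.32). The control ratios were above every TLX1 negative tumour for *Gapdh* in TLX1 tumours 2, 5 and 6 (2.86, 2.37 and 1.87, against at most 0.71) and for *Actb* in tumours 2, 3, 5 and 6 (2.72, 1.31, 2.73 and 2.00, against at most 1.22).

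The first pattern weighed is the TLX1 difference, for which the random-block test, the test on genes chosen in tumours 2, 5 and 6 and the counts without 3 TLX1 tumours were picked after the result was seen. Of 100 splits of single tumours, the real one included, 2 called as many genes (1889, highest other 2286). That is under the limit set beforehand, but splits that mix backgrounds cannot exclude chance between whole backgrounds. RNA degradation stays open, with 132 genes called without TLX1 tumours 2, 5 and 6 and 1388 without tumours 1, 3 and 4: the planned ratios of the called genes' medians in TLX1 tumours 1, 3 and 4 to those in tumours 2, 5 and 6 (0.803 for higher and 0.583 for lower genes) decide nothing, because all 6 tumours chose those genes. Genes chosen in tumours 2, 5 and 6 alone, and measured from negative tumours not used to choose them, kept 0.523 (800 higher genes) and 0.352 (857 lower genes) of their difference in tumours 1 and 4, but the lower genes kept 0.177 in tumour 1 and 0.505 in tumour 4 (higher genes 0.430 and 0.606), so the tumours disagree and neither degradation nor its absence is excluded. A difference of this 1 background, whatever its TLX1 status, also stays open: 2 genes remain with background as a random block, but no other background split off the same way calls as many (*Cdkn2a* knockout, 9 tumours, 1674; backgrounds of 3 tumours 3 to 521).

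The second pattern is *Lmo1*, high in tumours labelled Nup98HoxD13 and low in those labelled olig1-LMO1, whose tests by whole-profile correlation and by *Lmo1* level were chosen after the result was seen. An exchange of labels is a candidate explanation: tumours labelled Nup98HoxD13 correlate more with LMO1 transgenic tumours, by 0.177 in mean r, and in the other group *Hoxa5* and *Hoxc4* are high in tumours 2 and 3 (185 and 208, 315 and 710) but not in tumour 1 (1.70 and 1.95). The correlation is not particular to LMO1: mean r is 0.190 for LMO1 with labelled Nup98HoxD13, 0.186 for LMO1 with Pokemon and 0.185 for labelled Nup98HoxD13 with Pokemon. *AI506816* is low in every LMO1 and labelled Nup98HoxD13 tumour and high in every tumour labelled olig1-LMO1 (5.55 ± 0.29 against LMO1). It is also low in TLX1, p53, ThPOK, Pokemon and Ikaros Plastic tumours, so it is not particular to LMO1 either. No test of the exchange used this gene. A test planned on the E protein genes gave −0.147 over 3334 genes, against the exchange, but it cannot tell, because a check added afterwards found that LMO1 tumours left out of the gene choice score only −0.03 to 0.07 over 3442 genes, inside the range of tumours outside that axis. The alternative that *Lmo1* is active in correctly labelled Nup98HoxD13 tumours also stays open. Their lowest signal is 2.36 times the highest of the 38 tumours outside LMO1 transgenic and these labels. Its rule also asked for high *Lmo1* in tumours labelled olig1-LMO1, where it is 11.1 to 34.3, so that part failed. Nothing here decides between them, and no tumour was moved.

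The third pattern is a set of gland genes high in Ikaros Plastic tumour 2 and *Cdkn2a* knockout tumour 8, whose tests were written before their results were seen, while genes already named were taken out of the marker list afterwards. *Mucl2* reads 9360 and 7547 there and *Scgb1b27* 8926 and 8699. Salivary or lacrimal gland tissue in the sample is a candidate explanation that fits: for 17 of 25 gland markers, these 2 tumours are the highest of 47, led by *Klk1* (10345 and 7118), *Car6* (9071 and 7605) and *Pip* (8860 and 7030), with 0 of the markers in the T cell lists. Scaling of the arrays does not account for it, since *Prol1* differs by log2 8.06 after quantile normalization and 8.03 before. *Mucl2* also reads 2725 and 1018 in the other Ikaros Plastic tumours and 1773 in *Cdkn2a* knockout tumour 1, which the test does not address.

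Splits of the labels, all planned, gave these counts of orders with as many called genes, of 100 with the real one included. Each share of 100 was under the limit set beforehand. Orders that mix backgrounds cannot say how often whole backgrounds would differ as much by chance. For LMO1 and labelled olig1-LMO1 another order called more genes than the real one, and the tests were not adjusted for their number. The real count and the highest other were 2777 and 63 for TLX1 (1 order), 1915 and 1000 for p53 (1), 1041 and 13 for ThPOK (1), 91 and 1238 for LMO1 (3), 588 and 229 for Tal1-LMO2 (1), 58 and 162 for labelled olig1-LMO1 (4), 265 and 35 for labelled Nup98HoxD13 (1), 2013 and 1372 for Ikaros Plastic (1), 1657 and 1527 for beta-catenin (1) and 2704 and 4 for *Cdkn2a* knockout (1). Why an order gave 1238 calls for LMO1 was not examined. For labelled olig1-LMO1 against LMO1 the 10 possible splits are too few to tell (1 with as many; 85 and 2).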

How the results depend on the processing

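Directions held better than counts. Counts of called genes and lists within 1.5 times the reported count were 20 of 22 with a pseudocount of 1, 17 of 22 with the median, 14 of 23 after quantile normalization, 17 of 18 without a filter and with the filter of 6 arrays, 14 of 18 with the probe set of largest interquartile range, 18 of 18 without trend and 16 of 18 with the 3'/5' covariate. Dim genes are limited by the array background, which is why a gene was tested only where its signal exceeded the array median in at least 2 arrays. Tested genes can still lie under the median in most arrays. For each changed value below, the cause was not tested.

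With a pseudocount of 1, rag E2A knockout gave 301 called genes, Tal1-LMO2 against Tal1 105, and *Zbtb7b* turned to 0.20. With the median, Tal1-LMO2 gave 319, E2A knockout 219, rag E2A knockout 42, Tal1-LMO2 against Tal1 8, and the lists of the 14 backgrounds 4. After quantile normalization the counts were Tal1 101, Tal1-LMO2 265, labelled olig1-LMO1 38, E2A knockout 153, rag E2A knockout 49, labelled Nup98HoxD13 101, targeted genes 3, Tal1-LMO2 against Tal1 5 and lists 4. Without a filter Tal1-LMO2 against Tal1 gave 19, and with the filter of 6 arrays rag E2A against E2A knockout gave 2. The probe set of largest interquartile range gave LMO1 158, labelled olig1-LMO1 103, Pokemon 128 and labelled olig1-LMO1 against LMO1 137.

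The title number as a replicate block gave 1713 for *Cdkn2a* knockout and 13 for Tal1-LMO2 against Tal1, and 1714 for TLX1. The numbers do not pair the tumours: 230 same-number pairs had a mean residual r of −0.00, 27 of them over 0.1, and 1 of 47 tumours correlated best with its own number. For TLX1, background as a random block left 2 genes. *Notch1*, never called, turned negative with 14 background means (−0.34), the random block (−0.19), the 3'/5' covariate (−0.35), without TLX1 tumours 1, 3 and 4 (−0.40), without the beta-catenin background (−4.2e-05) and without the *Cdkn2a* background (−0.48). Its leave-one-out values run from −0.12 to 0.69, and that of −0.04 also turned. Camera with the preset correlation called 5 lists for TLX1 and 122 over the 14 backgrounds, and fry 2 and 67, against 0 and 2 with an estimated correlation.

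Alternatives chosen after the data were seen: without the 3 TLX1 tumours of high ratio 132 genes, without the 3 others 1388 (*Cdkn2a*, not called, at −0.0468), and with the covariate 6 for TLX1 positive against negative and 309 for TLX1 against the 13 other backgrounds, with *Ctse* at 0.31 and *Ikzf1* at 0.38. Without the tumours labelled Nup98HoxD13 and olig1-LMO1, LMO1 gave 153. Without p53 knockout 2, Ikaros Plastic 2 and *Cdkn2a* knockout 8 the counts were p53 726, ThPOK 1584, LMO1 200, Tal1-LMO2 939, labelled olig1-LMO1 110, E2A knockout 659, rag E2A knockout 368, labelled Nup98HoxD13 454, Pokemon 141 and Ikaros Plastic 1012.

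With 1 sample left out at a time, counts ran from 1224 to 1869 for TLX1 positive against negative, 2128 to 2814 for TLX1 against the other backgrounds, 580 to 2414 for p53, 274 to 475 for ThPOK, 127 to 277 for Tal1, 13 to 42 for LMO1, 150 to 325 for Tal1-LMO2, 16 to 29 for labelled olig1-LMO1, 23 to 233 for E2A, 11 to 40 for rag E2A, 67 to 142 for labelled Nup98HoxD13, 6 to 12 for Pokemon, 526 to 1655 for Ikaros Plastic, 718 to 944 for beta-catenin and 2319 to 2669 for *Cdkn2a*. The same ranges were 3 to 43 for Tal1-LMO2 against Tal1, 37 to 80 for labelled olig1-LMO1 against LMO1 and 3 to 16 for rag E2A against E2A knockout. Where 1 sample of a background remained, it was assumed to vary like the other groups. The similarity count of 30 was 29 with Spearman correlation, 34 with the 1000 most variable genes and 30 after quantile normalization.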

Other observations

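A contrast of backgrounds linked to E protein activity gave many calls, though not all 6 of its backgrounds follow it. Tal1, LMO1 and LMO2 act on E protein complexes, and E2A is an E protein, so Tal1, LMO1, Tal1-LMO2, labelled olig1-LMO1, E2A knockout and rag E2A knockout were set against the other 7 TLX1 negative backgrounds, a contrast fixed before the values were seen. *H2-T3* (3.18 ± 0.37), *H2-T18* (2.99 ± 0.42), *Ly6d* (2.98 ± 0.63), *Gdpd3* (2.97 ± 0.35) and *Erdr1* (2.94 ± 0.29) rose, and *Mndal* (−3.05 ± 0.39), *H2-Eb1* (−3.01 ± 0.31), *Myzap* (−2.53 ± 0.31), *Gfra1* (−2.40 ± 0.31) and *Anxa5* (−2.29 ± 0.22) fell. H2 genes differ between strains, which the labels do not give. Among the 6 backgrounds *AI506816* is low in LMO1 and high in the rest. Among the other 7 it is high only in beta-catenin and *Cdkn2a* knockout tumours. The contrast therefore cannot separate a link to E proteins from a difference of strain. DNA replication genes were higher in 18 of 30 (14 after quantile normalization), and stroma markers lower in 13 of 18 (10), myeloid markers in 14 of 23 (13) and early thymic progenitor genes in 9 of 15 (3). Ribosomal protein genes were higher in 19 of 20 but in 2 of 20 after quantile normalization. These list counts are of called members and are not list tests. In all 3312 of 8810 genes were called, 1201 higher and 2111 lower. Of the 3312, 36.3% were higher, against 59.8% of 2314 after quantile normalization, which moved the median of all genes from −0.07 to 0.04.

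Both tests of this contrast were written beforehand. Of 100 orders of the labels 1, the real one, called as many genes (3312 against 108), but such orders mix tumours of different backgrounds. Another choice of 6 of the 13 backgrounds gave as many calls in 2 of 100 draws, the real one included (highest other 3501, median 426), so the grouping is unusual but not the only large division. LMO1 transgenic tumours, left out of the gene choice, scored −0.03 to 0.07 on the genes of the contrast, against 0.46 to 0.65 for the tumours of Tal1, Tal1-LMO2, E2A knockout and rag E2A knockout and at most 0.12 outside the contrast. Tumours labelled olig1-LMO1 scored 0.106 to 0.265 when left out. Those 4 backgrounds helped choose the genes, so their own scores test nothing.

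*Notch1* and *Dtx1* were low in both beta-catenin and *Cdkn2a* knockout tumours, while the Notch pathway list was called in neither. The mean r between these backgrounds is 0.241, rank 6 of 91 pairs. *Notch1* read 54.3 to 124 in the former and 42.0 to 246 in 8 of the 9 latter, against a median of 2426 (lowest 160) in the 35 tumours of other backgrounds, and *Dtx1* 84.9 to 112 and at most 133, against 2321 (lowest 27.4). *Cdkn2a* knockout tumour 7 read 1537 for *Notch1* and 2175 for *Dtx1*, and beside the median of those 35 tumours 486 against 398 for *Ptcra*, 132 against 250 for *Hes1*, 109 against 770 for *Notch3* and 39.9 against 234 for *Il2ra*. The mean r of the 2 groups exceeds the highest mean r of an Ikaros Plastic tumour with either by 0.131, in a test chosen after the result was seen.

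*AI506816* split the backgrounds cleanly: at most 33.0 in every TLX1, p53, ThPOK, LMO1, labelled Nup98HoxD13, Pokemon and Ikaros Plastic tumour, and at least 381 in every tumour of the other 7 backgrounds. The labels give no mouse strain, and whether this split follows strain was not tested. Ikaros Plastic 2 and *Cdkn2a* knockout 8 are each other's nearest tumour (r = 0.563). LMO1 transgenic and labelled Nup98HoxD13 tumours rank 8 of 91 pairs (mean r = 0.190), next to LMO1 with Pokemon (0.186) and labelled Nup98HoxD13 with Pokemon (0.185).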
